A study of Mus musculus with 8 samples.

How the data were processed

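Bulk RNA sequencing was used to measure 8 mouse tumours from a conditional model in which Cre recombinase, delivered by an adenovirus injected into the peritoneal cavity, recombines floxed alleles of Nf2 and Cdkn2a, per the labels. In 3 primary tumours (19, 20 and 127) Pak2 was wild-type, and in 4 primary tumours (13, 14A, 59 and 61) the labels give Pak2 as floxed and deleted. A secondary tumour, 14B, carries the same Pak2 label as these 4. The labels do not say that the tumours of a group came from separate animals, so every p-value measures the spread between these samples.

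Per the labels' protocols, tumours were stored at low temperature in an RNA preservative and ground in liquid nitrogen, total RNA was column-purified, and mRNA-enriched, fragmented and PCR-amplified Illumina libraries were made by a sequencing company. The authors deposited a table of unnormalised read counts per gene, with 1 column per tumour and no tumours pooled. Per the submitters' processing notes, STAR and HTSeq were used with the genome builds GRCm38 and mm10. The versions, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense neighbour cannot be told apart, and genes with a near-identical copy elsewhere are reported as uncertain. The table also holds a gene length in bases, used only for a check of length bias. It had 8 count columns, 0 columns of other samples, 0 entries that name no gene, 0 identical columns and 70 repeated gene names, so genes were followed by their Ensembl identifiers. Of 35275 identifiers, 34490 (97.8%) were found in the GENCODE M21 annotation of GRCm38, and 99.8% of those overlapped at the same place. Coordinates are those of the deposited table.

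Total counts ranged from 13469851 in tumour 14B to 20402401 in tumour 14A. A gene with no counts in a tumour could still be present at up to 3 counts, a floor of 0.139 to 0.193 CPM (counts scaled to library size) in the 7 primary tumours and 0.311 CPM in tumour 14B. Floors cover counting error only, since PCR copies of a molecule are counted separately. No tumours were copies of each other: the mean chi-square per gene between the most similar pair, tumours 59 and 61, was 99.5.

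The primary comparison set the 4 tumours labelled Pak2-null against the 3 wild-type tumours. Counts were fitted with edgeR 4.0.16 in R 4.3.3 with TMM normalisation and no covariate, since no label gives a batch. Genes entered with filterByExpr (minimum count 10, minimum total count 15), which left 15412 of 35275. Differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are labelled Pak2-null minus wild-type, and the standard error (SE) is the size of the log2 fold change divided by the square root of its F statistic. CPM values use library sizes over the tested genes and TMM factors over all 8 tumours. The log2 CPM used a prior count of 2. Single values were compared by an exact two-sided permutation test, whose smallest possible p for 3 against 4 tumours is 0.0571.

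Before the data were examined, 38 gene lists were fixed, covering pathways, tumour programmes, markers of other cell types and tissues, and RNA handling. Each list with at least 3 tested members was put to limma 3.58.1's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists tested. The targeted genes, the PAK family and the sex genes were described by value only. The liver list had too few tested members for a test. Ca9, Ahsp and Epb42 were not found under these names. A list's score in a tumour is the mean log2 CPM of its tested members. Camera with an estimated correlation, camera on ranks and fry were alternatives.

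Genes named in the text follow a rule fixed before the data were examined. It takes Pak2, Nf2 and Cdkn2a, and a set of Hedgehog, Wnt, growth and mesothelial genes. It takes up to 10 genes per direction with the largest change among those that passed, with a mean log2 CPM of at least 1, groups that did not overlap and an informative symbol, filled up by lowest p. It adds up to 4 tested members of each list with the lowest p, and 10 genes per direction for tumour 14B, with a mean log2 CPM of at least 3. Genes outside this rule are said to have been chosen after their values were seen. Tumour 14B was compared without a test, as differences of log2 CPM and as percentiles of list medians among 10000 random lists matched on expression.

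Near-identical copies were found with BLAST 2.17.0 (megablast) by aligning 395 genes, the tested pseudogenes and the genes called, to transcripts of tested protein-coding genes, keeping matches with at least 95% identity over at least 80% of the copy. Ratios of a copy to its parent used CPM plus 0.5.

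Other choices fixed before the data were examined were other normalisations (median-of-ratios size factors, upper quartile, library size), no filter and a stricter filter (CPM of at least 1 in at least 3 tumours), DESeq2 1.42.0, limma-voom with and without sample quality weights, robust dispersion, leaving out each primary tumour, other ways of using tumour 14B, other thresholds, and a sex covariate. After the data were seen, 4 more were added: leaving out tumours 14A and 127 together, taking out genes of other tissues, and 2 versions of summing near-identical copies. The count of genes and the list tests were also repeated for all 35 splits of the 7 primary tumours into 3 and 4.

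The edgeR and camera steps were tested on counts simulated for the 15412 genes of the primary comparison. Of 50 genes changed at each size, 28.0% were called at 4-fold, 82.0% at 16-fold, 94.0% at 64-fold and 100% at 256-fold, and 11 unchanged genes were called. A list shifted on purpose reached an adjusted p of 5.89e-14 by camera, and 0 of 33 other lists passed. These lists were random and genes were simulated independently of each other. False calls of lists whose genes move together were therefore not tested. Across tested genes, which are not independent replicates, gene length and log2 fold change had a Spearman correlation of -0.00687.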

Results

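Pak2, which encodes a p21-activated kinase acting downstream of Rac and Cdc42, was transcribed in all 8 tumours, including the tumours labelled Pak2-null. Its transcripts stood at 128, 90.1 and 92.7 CPM (counts scaled to library size) in wild-type tumours 19, 20 and 127. They stood at 186, 238, 165 and 131 CPM in primary tumours 13, 14A, 59 and 61, which are labelled Pak2-null, and at 239 CPM in the secondary tumour 14B. The group means were 103 ± 20.9 against 180.0 ± 44.9 CPM (mean ± SD of 3 and of 4 tumours), a log2 fold change of 0.82 (SE 0.28) toward the tumours labelled Pak2-null. That difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.267), and with any 1 tumour left out the log2 fold change ran from 0.66 to 0.98. Of the alternatives only limma-voom with quality weights and Benjamini-Hochberg adjustment passed Pak2 (log2 fold change 0.81, adjusted p = 0.0480, with values up to 0.652 in the 23 alternatives). Pak2 transcripts were therefore not lower in the tumours labelled Pak2-null. Counts per gene do not show whether a floxed exon is missing from these transcripts, and the label is used as given.

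Nf2, which encodes the tumour suppressor Merlin, stood at 119 ± 20.0 CPM in the wild-type tumours and 99.97 ± 20.2 CPM in the tumours labelled Pak2-null. Cdkn2a, which encodes the cell cycle inhibitor p16Ink4a and the p53 activator p19Arf, was low in both, at 2.84 ± 0.409 and 4.87 ± 0.749 CPM. Their log2 fold changes were -0.23 (SE 0.24) and 0.80 (SE 0.36), with adjusted p values of 0.728 and 0.411 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the other PAK genes, Pak1 and Pak4 were transcribed in every tumour, with log2 fold changes of 0.20 (SE 0.23) and 0.81 (SE 0.47). Pak3 had a log2 fold change of -0.83 (SE 0.99). Pak6 reached at most 43 counts, in tumour 61, and Pak7 at most 3, in tumour 20.

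The closest tumours were 14A and 14B, for which the labels do not say whether they come from 1 animal, with a Spearman correlation of 0.962 across genes, followed by wild-type tumours 20 and 127 (0.954) and by 59 and 61 (0.946). The lowest correlation, 0.746, was between tumours 127 and 14A. The tumours did not group by label throughout. Wild-type tumour 19 was closer to tumours 61 (0.901) and 59 (0.899) than to wild-type tumours 20 (0.888) and 127 (0.870). Tumour 14A stood at 0.802, 0.850 and 0.817 with tumours 13, 59 and 61, which share its label. The first 2 principal components held 41.2% and 27.3% of the variance. Xist, the RNA that silences an X chromosome in females, stood at 151, 459 and 26.6 CPM in tumours 19, 20 and 127, and between 0.0619 and 1.33 CPM in the primary tumours labelled Pak2-null. The Y-linked helicase gene Ddx3y stood at 1.62 and 1.24 CPM in tumours 19 and 20, at 116 CPM in tumour 127, and from 85.4 to 104 CPM in the primary tumours labelled Pak2-null. Tumours 19 and 20 thus had the female pattern, tumour 127 had transcripts of both kinds, and every tumour labelled Pak2-null had the male pattern.

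Of the genes tested, 8 fell in the tumours labelled Pak2-null, among them signalling and cytoskeletal genes that were well transcribed in all 3 wild-type tumours. Adcy2, which encodes an adenylyl cyclase that makes cyclic AMP, went from 21.2 ± 8.42 to 0.472 ± 0.177 CPM. Limch1, whose product binds actin and activates non-muscle myosin II, went from 93.9 ± 42.9 to 6.85 ± 2.33 CPM, and Gprc5c, an orphan receptor gene, from 70.9 ± 36.7 to 5.60 ± 1.24 CPM. The 3 genes that rose are all near-identical copies of genes elsewhere: Rps3a2 and Rps3a3, copies of the ribosomal protein gene Rps3a1, and Tpm3-rs7, a copy of the tropomyosin gene Tpm3.

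Adamts20, which encodes a secreted metalloprotease of the matrix, fell from 39.6 ± 23.0 to 1.05 ± 0.429 CPM. Alpk2, an alpha-kinase gene, fell from 20.0 ± 1.05 to 1.003 ± 0.491 CPM, and Lypd6, whose product sits at the cell surface and enhances Wnt receptor signalling, from 9.12 ± 2.58 to 0.371 ± 0.155 CPM. The log2 fold changes were -5.45 (SE 0.50) for Adcy2, -5.21 (SE 0.56) for Adamts20, -4.58 (SE 0.51) for Lypd6, -4.29 (SE 0.47) for Alpk2, -3.75 (SE 0.41) for Limch1 and -3.64 (SE 0.39) for Gprc5c. The 2 copies that fell were Gm11868, near-identical to the cytochrome b5 reductase gene Cyb5r4, from 7.33 ± 2.48 to 0.0710 ± 0.0212 CPM (1 or 2 counts a tumour), and Gm5900, near-identical to the mTOR pathway gene Lamtor3, from 8.92 ± 1.22 to 0.645 ± 0.0906 CPM. Their log2 fold changes were -6.52 (SE 0.52) and -3.75 (SE 0.37). Among the rising copies Rps3a3 went from 3.81 ± 2.45 to 329 ± 53.1 CPM, Rps3a2 from 3.98 ± 0.910 to 112 ± 33.5 CPM and Tpm3-rs7 from 5.70 ± 3.54 to 334 ± 82.1 CPM, log2 fold changes of 6.45 (SE 0.58), 4.84 (SE 0.34) and 5.89 (SE 0.65).

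These 5 copies match their parent genes at 97.98% (Gm11868), 98.87% (Rps3a3), 99.1% (Tpm3-rs7), 99.47% (Gm5900) and 99.5% (Rps3a2) of aligned bases, so their counts are uncertain. Rps3a1 itself stood at 961 CPM against 211 CPM, a log2 fold change of -2.17 (SE 0.28). With the copies added to their parents the log2 fold changes were -0.55 (SE 0.28) for the Rps3a family, 0.35 (SE 0.38) for Tpm3, 0.56 (SE 0.29) for Cyb5r4 and -0.04 (SE 0.21) for Lamtor3.

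The 6 falling genes other than the copies lie apart in the genome (GRCm38): Adcy2 (ENSMUSG00000021536) on chromosome 13, 68620043 to 68999541; Adamts20 (ENSMUSG00000022449) on chromosome 15, 94270163 to 94465418; Lypd6 (ENSMUSG00000050447) on chromosome 2, 50066429 to 50193569. Alpk2 (ENSMUSG00000032845) lies on chromosome 18, 65265529 to 65393888, Limch1 (ENSMUSG00000037736) on chromosome 5, 66745835 to 67057159 and Gprc5c (ENSMUSG00000051043) on chromosome 11, 114851152 to 114872617. The copies that rose are Rps3a3 (ENSMUSG00000059751, chromosome 13, 108670603 to 108671397), Rps3a2 (ENSMUSG00000062611, chromosome 14, 88123017 to 88123808) and Tpm3-rs7 (ENSMUSG00000058126, chromosome 14, 113314608 to 113316713). Those that fell are Gm11868 (ENSMUSG00000050550, chromosome 4, 18844202 to 18845679) and Gm5900 (ENSMUSG00000094685, chromosome 7, 104949176 to 104950441).

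In total 11 of 15412 tested genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 higher and 8 lower, with adjusted p from 0.0224 to 0.0436. At unadjusted p under 0.05 there were 1995 genes, 677 higher and 1318 lower. The groups did not overlap in all 11 of these genes and in 2158 tested genes (14.0%). Chance alone gives 5.71% on average over splits of the tumours. The share was not counted for other splits, so an excess over chance was not tested. DESeq2 called 1196 genes and limma-voom 25, both lists weighted toward lower genes (76.3% and 80%), against 72.7% by edgeR. Leaving out tumour 19 gave 59 genes, and leaving out 20, 13, 59 or 61 gave 0, leaving out 127 gave 1 and leaving out 14A gave 8. With the copies summed, 0 genes passed edgeR's test and 1988 had an unadjusted p under 0.05, because the 5 copies left the test and the p values of the other 6 genes no longer sufficed. All 11 genes kept their direction in every alternative that tested them, which groups that do not overlap all but fixed in advance. Adcy2 passed in 15 of 23 alternatives and Adamts20 in 11 of 23.

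Further genes had large differences without passing edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Igf2, a fetal growth factor gene, stood at 2781 ± 1886 CPM in the wild-type tumours and 7.04 ± 6.90 CPM in the tumours labelled Pak2-null, and Sox11, a transcription factor gene of embryonic progenitors, at 58.5 ± 33.6 and 0.661 ± 0.583 CPM. Rragd, which encodes a GTPase that recruits mTORC1 to lysosomes, stood at 78.5 ± 17.8 and 2.57 ± 2.00 CPM, and Fam101b, a gene of actin filament organisation, at 103 ± 7.91 and 32.9 ± 5.26 CPM. Log2 fold changes of these 4 were -8.61 (SE 1.05), -6.44 (SE 0.79), -4.90 (SE 0.60) and -1.62 (SE 0.20), each with adjusted p = 0.0540 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the other direction were the homeobox genes Hoxb7 (3.47 ± 0.573 and 17.9 ± 3.56 CPM) and Hoxb6 (4.39 ± 0.525 and 16.5 ± 1.38 CPM) and Cd38 (17.0 ± 5.58 and 72.3 ± 22.2 CPM), which encodes an NAD-consuming surface enzyme. Slc4a8, a bicarbonate transporter gene, and Gsg1 had log2 fold changes of 2.22 (SE 0.37) and 4.37 (SE 0.62). Gzmg, a granzyme gene of cytotoxic lymphocytes, had 0 counts in all 3 wild-type tumours, where up to 3 counts (0.139 to 0.193 CPM) could have been missed, and 4.10 ± 1.42 CPM in the tumours labelled Pak2-null. Its neighbour Gzmf stood at 0, 0 and 0.0642 CPM against 5.53 ± 1.64 CPM. Adjusted p values in this direction ran from 0.0544 (Gzmf) to 0.103 (Cd38) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

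**Figure D1:**
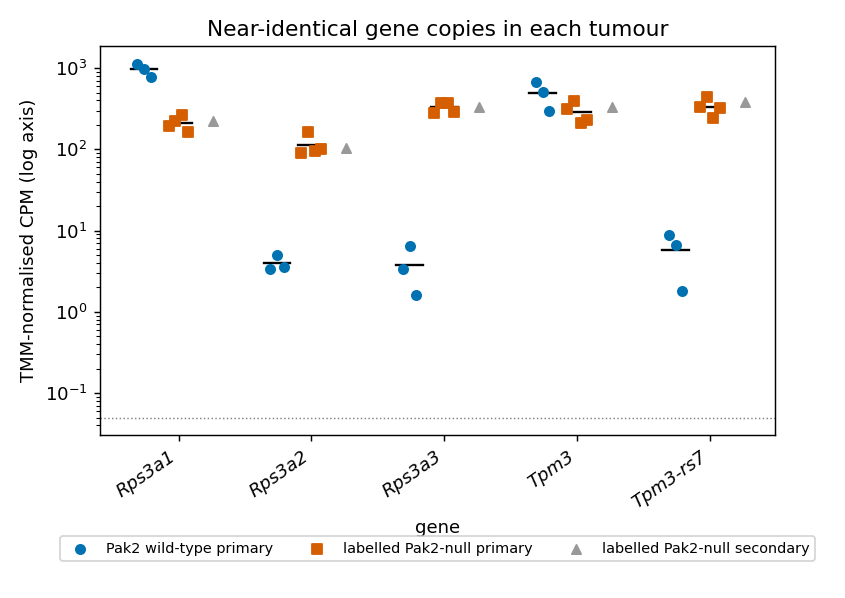
Normalised CPM of Rps3a1, its copies Rps3a2 and Rps3a3, and Tpm3 with its copy Tpm3-rs7 in 3 wild-type primary tumours (blue circles), 4 primary tumours labelled Pak2-null (orange squares) and 1 secondary tumour (grey triangle). Black bars are group means, and values under 0.05 CPM are drawn on the dotted line.

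Hedgehog pathway genes fell as a list in the tumours labelled Pak2-null, with an adjusted p of 0.00153 by limma's camera with Benjamini-Hochberg adjustment. With an estimated correlation the adjusted p was 0.637. Gli1, a transcription factor gene that Hedgehog signalling switches on, stood at 27.9 ± 30.3 CPM in the wild-type tumours and 1.97 ± 1.31 CPM in the tumours labelled Pak2-null. Gli2, the main activator of the pathway, reached 883 CPM in tumour 19, 13.3 in tumour 20 and 18.4 in tumour 127, against 6.90 ± 5.33 CPM. Cdon, which encodes a co-receptor for Hedgehog ligands, stood at 127 ± 84.0 and 18.3 ± 7.89 CPM. The receptor gene Ptch1, itself a target of the pathway, reached 205 CPM in tumour 19 and 10.3 and 12.4 CPM in tumours 20 and 127, and from 7.97 to 9.82 CPM in the tumours labelled Pak2-null.

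Log2 fold changes were -3.80 (SE 0.98) for Gli1, -5.45 (SE 1.62) for Gli2, -2.78 (SE 0.52) for Cdon and -3.08 (SE 1.02) for Ptch1. Scube3 and Scube1, which encode secreted proteins that help release Hedgehog ligands, were at -3.08 (SE 0.83) and -2.04 (SE 0.59). Without tumour 19 the values were -2.39 for Gli1, -1.20 for Gli2, -0.35 for Ptch1 and -1.92 for Scube3. The pathway inhibitor gene Hhip stood at 51.2 CPM in tumour 19 and under 1 CPM elsewhere, too low for a test. Smo, the signal transducer, and Gli3, mainly a repressor, had log2 fold changes of -0.51 (SE 0.63) and 0.12 (SE 0.67). Of 22 tested members 16 had a lower and 6 a higher mean, with a median log2 fold change of -0.61 and a mean of -1.28.

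No Hedgehog gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, with adjusted p from 0.110 (Cdon) upward, and 9 members, all lower, had an unadjusted p under 0.05. Adjusted over the list alone, 5 passed: Cdon, Gli1, Gli2, Scube1 and Scube3. The mean log2 CPM of the list was 4.79, 3.79 and 3.98 in tumours 19, 20 and 127 and 2.995, 1.91, 3.51 and 3.43 in tumours 13, 14A, 59 and 61 (exact permutation p = 0.0571, the smallest possible). Leaving out tumour 14A ended the list's call (adjusted p = 0.227 by camera with Benjamini-Hochberg adjustment), and leaving out any other tumour did not. Over all 22 alternatives the adjusted p of the list ran from 2.49e-04 to 0.637.

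**Figure D2:**
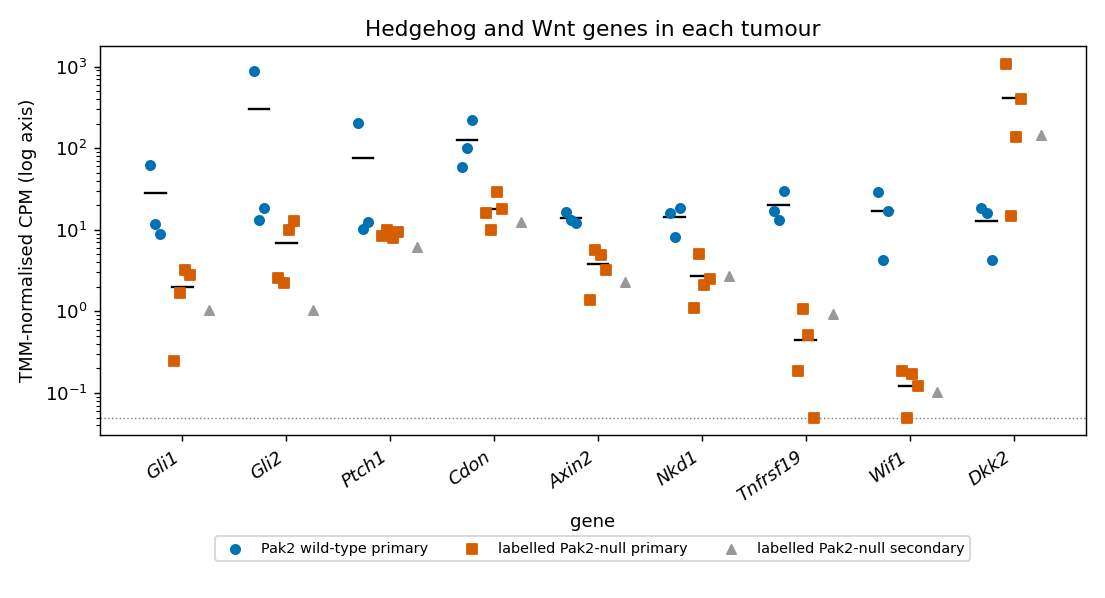
Normalised CPM of Hedgehog genes (Gli1, Gli2, Ptch1, Cdon) and Wnt pathway genes (Axin2, Nkd1, Tnfrsf19, Wif1, Dkk2) in 3 wild-type primary tumours (blue circles), 4 primary tumours labelled Pak2-null (orange squares) and 1 secondary tumour (grey triangle). Black bars are group means, and values under 0.05 CPM are drawn on the dotted line.

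Wnt ligands and receptors fell as a list and so did Wnt antagonists, by camera with Benjamini-Hochberg adjustment (adjusted p = 4.66e-04 and 0.0440). Estimating the correlation gave an adjusted p of 0.637 for both. Porcn, which encodes the enzyme that lipid-modifies Wnt ligands for release, stood at 25.1 ± 12.9 CPM in the wild-type tumours and 5.65 ± 2.38 CPM in the tumours labelled Pak2-null, and the Wnt receptor genes Fzd9 and Fzd4 at 10.3 ± 7.09 and 39.3 ± 13.5 CPM against 0.348 ± 0.280 and 15.2 ± 3.78 CPM. Wif1 and Shisa2, whose products hold back Wnt signalling outside the cell and at its receptors, stood at 16.9 ± 12.5 and 42.6 ± 21.3 CPM against 0.121 ± 0.0848 and 1.27 ± 1.01 CPM. Dkk2, which encodes a secreted ligand of Wnt co-receptors, stood at 12.9 ± 7.66 CPM against 408 ± 475 CPM, with 1078 CPM in tumour 13 and 15.0 CPM in tumour 14A. Among beta-catenin targets the feedback inhibitor genes Axin2 and Nkd1 stood at 14.0 ± 2.10 and 14.3 ± 5.43 CPM against 3.81 ± 1.94 and 2.69 ± 1.67 CPM.

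Of ligands and receptors 22 of 32 tested members were lower, with a median log2 fold change of -0.68. Porcn, Fzd9, Fzd4 and Fzd8 had log2 fold changes of -2.13 (SE 0.49), -4.85 (SE 1.15), -1.35 (SE 0.32) and -1.99 (SE 0.74). Of antagonists 9 of 13 were lower, with a median of -0.78. Wif1, Shisa2, Sfrp5 and Dkk2 were at -7.05 (SE 1.03), -5.05 (SE 0.75), -4.11 (SE 1.304) and 5.01 (SE 1.45), with Sfrp5 at -2.50 without tumour 19 and Dkk2 at 3.85 without tumour 13. Beta-catenin targets did not pass (adjusted p = 0.440 by camera with Benjamini-Hochberg adjustment, 0.849 with an estimated correlation). Their median log2 fold change was above 0 (0.44), while their mean (-0.33) and the test pointed down, since a few members were far lower.

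Within the beta-catenin list Tnfrsf19, Nkd1 and Axin2 had log2 fold changes of -5.42 (SE 1.07), -2.38 (SE 0.57) and -1.86 (SE 0.50). The hyaluronan receptor gene Cd44, the cyclin gene Ccnd1 and Myc were at 1.71 (SE 0.50), 1.24 (SE 0.44) and 0.87 (SE 0.46), and the Wnt transcription factor gene Lef1 at 0.85 (SE 1.72). For a change in either direction fry gave the beta-catenin targets an adjusted p of 0.0104, and over its 22 alternatives the adjusted p of this list ran from 0.0104 to 0.893. No gene of the 3 Wnt lists passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Adjusted over each list alone, 3 ligand and receptor genes passed (Fzd4, Fzd9 and Porcn), 4 antagonists (Dkk2, Sfrp5, Shisa2 and Wif1) and 5 targets (Axin2, Cd44, Nkd1, Nkd2 and Tnfrsf19). At unadjusted p under 0.05 there were 5, 5 and 6. Leaving out tumour 14A ended the calls of the ligand and receptor list and of the antagonists (adjusted p = 0.0592 and 0.437 by camera with Benjamini-Hochberg adjustment), and leaving out tumour 19 or 61 also ended that of the antagonists (0.170 and 0.0619). Over 22 alternatives each, the adjusted p ran from 1.08e-04 to 0.637 for ligands and receptors and from 0.00110 to 0.637 for antagonists.

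Skeletal muscle genes fell as a list, with the lowest p by camera with Benjamini-Hochberg adjustment of all 34 lists (adjusted p = 6.31e-14). With an estimated correlation the adjusted p was 0.637. Ttn, the giant spring protein gene of the sarcomere, stood at 134, 2527 and 4122 CPM in tumours 19, 20 and 127 and between 2.11 and 52.3 CPM in the primary tumours labelled Pak2-null. Neb, Tnni2 and Mylpf, of the thin filament, its calcium switch and the fast myosin light chain, had log2 fold changes of -5.86 (SE 1.39), -5.57 (SE 1.38) and -6.00 (SE 1.54). Smooth muscle and filament genes shared this direction: Des, the muscle intermediate filament gene, stood at 1807 ± 1334 and 57.6 ± 36.5 CPM, and Hspb6, Sync and Mylk had log2 fold changes of -4.34 (SE 0.82), -4.38 (SE 0.87) and -1.89 (SE 0.44). Which kind of muscle these transcripts came from was not tested. Fat and red cell genes were also lower in the tumours labelled Pak2-null, with Lep, the fat hormone gene, at 10.4 ± 7.18 and 0.620 ± 1.09 CPM, the fatty acid carrier gene Fabp4 at 324 ± 214 and 76.2 ± 61.6 CPM, and the haemoglobin gene Hba-a1 at 1408, 94.0 and 117 CPM against 25.3 ± 17.4 CPM.

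Skeletal muscle genes held 0.328%, 3.79% and 2.78% of the counts of tumours 19, 20 and 127, and from 0.00125% to 0.0947% in the primary tumours labelled Pak2-null. This share separated the 2 groups as the scores of the Hedgehog list, the Wnt ligand and receptor list and the Wnt antagonist list did. By camera with Benjamini-Hochberg adjustment the adjusted p was 6.31e-14 for skeletal muscle (14 of 14 lower, median -5.98), 1.82e-07 for smooth muscle (9 of 10 lower, median -2.69), 1.10e-05 for adipocytes (13 of 15 lower, median -2.41) and 0.0116 for erythroid cells (4 of 4 lower, median -4.45). With an estimated correlation the adjusted p was 0.328 for smooth muscle and 0.637 for the other 3. The groups overlapped in adipocyte genes, with a mean log2 CPM of 4.36 in tumour 61 and 3.59 in wild-type tumour 127. No gene of these lists passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Adjusted over the list alone, 14 skeletal muscle, 9 smooth muscle, 0 adipocyte and 4 erythroid genes passed, and at unadjusted p under 0.05 there were 14, 9, 5 and 4. The erythroid call ended without tumour 19 (adjusted p = 0.211 by camera with Benjamini-Hochberg adjustment, from 0.00400 to 0.637 over 21 alternatives), and the other 3 lists passed without any 1 tumour.

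**Figure D3:**
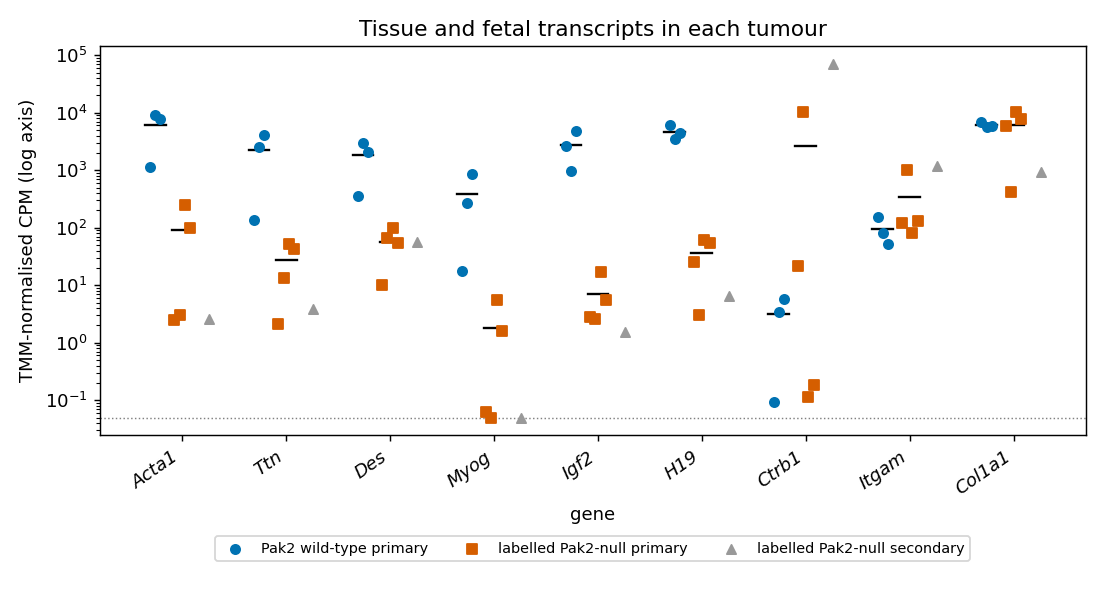
Normalised CPM of muscle (Acta1, Ttn, Des, Myog), fetal growth (Igf2, H19), pancreas (Ctrb1), myeloid (Itgam) and matrix (Col1a1) genes in 3 wild-type primary tumours (blue circles), 4 primary tumours labelled Pak2-null (orange squares) and 1 secondary tumour (grey triangle), some of them chosen after their values were seen. Black bars are group means, and values under 0.05 CPM are drawn on the dotted line.

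Outputs of MAPK signalling and genes of cytotoxic lymphocytes rose as lists in the tumours labelled Pak2-null by camera with Benjamini-Hochberg adjustment (adjusted p = 9.00e-04 and 3.88e-04). With an estimated correlation the adjusted p was 0.754 and 0.637. Dusp4, a phosphatase gene induced by ERK and acting back on it, stood at 18.3 ± 1.23 CPM in the wild-type tumours and at 159, 30.5, 140.1 and 113 CPM in tumours 13, 14A, 59 and 61. The ERK-induced transcription factor genes Etv4 and Etv5 and the phosphatase gene Dusp5 had log2 fold changes of 2.92 (SE 0.99), 1.07 (SE 0.37) and 1.88 (SE 0.54), against 2.62 (SE 0.55) for Dusp4. Prf1, the pore-forming protein gene of killer cells, stood at 1.19 ± 0.366 and 7.24 ± 4.69 CPM, and Il2rb, a receptor chain gene for interleukins 2 and 15, at 8.22 ± 3.01 and 33.1 ± 23.0 CPM. The killer cell genes Eomes and Klrb1c had log2 fold changes of 3.20 (SE 1.09) and 2.62 (SE 0.86).

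The MAPK list had 17 of 18 members higher, with a median log2 fold change of 1.15. Its mean log2 CPM in tumour 14A (3.53) was below those of the wild-type tumours (3.95 to 4.55). All 11 natural killer and cytotoxic genes were higher, with a median of 2.03, and their mean log2 CPM in tumour 13 (0.49) lay among those of the wild-type tumours (-0.21 to 0.85). Both lists passed without any 1 tumour. No gene of either passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, 1 (Dusp4) and 0 did adjusted over the list alone, and 8 and 5 had an unadjusted p under 0.05.

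Lists of fibroblasts and pericytes, the interferon response and the matrix fell as well, though the groups overlapped in all 3. The adjusted p with an estimated correlation was 0.637 for the first and 0.918 for the other 2. Among fibroblast and pericyte genes the mural cell receptor gene Notch3 and the proteoglycan gene Cspg4 stood at 141 ± 105 and 67.4 ± 23.8 CPM in the wild-type tumours and 29.6 ± 10.3 and 15.8 ± 8.96 CPM in the tumours labelled Pak2-null, and Pi16 and the potassium channel regulator gene Abcc9 had log2 fold changes of -1.95 (SE 0.65) and -0.98 (SE 0.34). The interferon-induced genes Ifi44, Ifit3, Mx2 and Rsad2 had log2 fold changes of -1.87 (SE 0.67), -0.86 (SE 0.46), -0.90 (SE 0.51) and -0.89 (SE 0.56). In the matrix list the collagen-binding proteoglycan genes Fmod and Ogn, the collagen gene Col14a1 and Mfap4 were at -4.65 (SE 1.03), -3.31 (SE 0.99), -1.09 (SE 0.27) and -2.12 (SE 0.93). By camera with Benjamini-Hochberg adjustment the adjusted p was 0.0168 for fibroblasts and pericytes (median -0.98, 8 of 12 lower), 0.0168 for the interferon response (median -0.40, 12 of 20 lower) and 0.0479 for the matrix (median -0.07, 23 of 40 lower). In mean log2 CPM the fibroblast and pericyte list stood at 6.91 in tumour 59 and at 6.499 to 6.85 in the wild-type tumours, with 0.894% against 0.133% to 0.178% of counts. The interferon list stood at 5.17 in tumour 14A against 4.64 to 4.99, and the matrix list at 8.87 and 8.82 in tumours 13 and 61 against 8.66 to 8.80.

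No gene of these 3 lists passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Adjusted over the list alone, 2 (Cspg4 and Notch3), 0 and 0 passed, and 7, 1 and 3 had an unadjusted p under 0.05. The fibroblast call ended without tumour 19 or 14A, the interferon call without 19, 20, 13 or 61, and the matrix call without 19, 20 or 127. Without tumour 14A the matrix list pointed up, with an adjusted p of 0.240 by camera with Benjamini-Hochberg adjustment (from 9.62e-04 to 0.983 over 22 alternatives).

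Markers of the mesothelium and general tumour programmes did not separate the groups as lists. Msln, which encodes mesothelin, ran from 1.11 CPM in tumour 13 to 132 CPM in tumour 61, and Wt1, a transcription factor gene of the mesothelium, had a log2 fold change of -0.66 (SE 0.87). Of YAP target genes Cyr61 was at -0.77 (SE 0.61), Ctgf at 0.58 (SE 1.01), Ccdc80 at -1.46 (SE 0.39), Tgfb2 at -2.47 (SE 0.67), Gadd45a at -2.81 (SE 0.80) and Axl, a receptor tyrosine kinase gene, at 1.60 (SE 0.50). The SRF target genes Cnn1, Myl9, Tpm2 and Actg2, which encode contractile proteins, were at -2.43 (SE 0.57), -2.13 (SE 0.52), -3.15 (SE 0.94) and -2.44 (SE 0.73). Cnn1 and Actg2 are also in the smooth muscle list, so the SRF and smooth muscle lists are not separate results. Fibronectin (Fn1) ran from 1494 CPM in tumour 14A to 39431 CPM in tumour 13, and its receptor chain gene Itga5 had a log2 fold change of 1.72 (SE 0.57).

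Twist2 and Cdh11, of mesenchymal cells, were at 2.50 (SE 1.42) and -1.29 (SE 0.62). The keratin genes Krt19 and Krt7 and the junction and mucin genes Cldn3, Cldn7 and Muc1 were at -2.57 (SE 1.21), -2.02 (SE 1.01), -2.44 (SE 1.64), -1.36 (SE 0.95) and -1.75 (SE 1.13). Of division genes Pcna, Rrm2, Tk1 and E2f1 were at 0.56 (SE 0.43), -0.46 (SE 0.34), 0.52 (SE 0.48) and 0.42 (SE 0.44). The p53 targets Cdkn1a, a cell cycle inhibitor gene, and Bax, a death effector gene, were at -1.66 (SE 0.47) and 0.72 (SE 0.25), with Zmat3 and Eda2r at 1.09 (SE 0.43) and -2.01 (SE 0.99). Bnip3, a mitophagy gene induced by hypoxia, was at -1.06 (SE 0.24), and Egln3, Ero1l and Adm were at -1.53 (SE 0.81), 0.68 (SE 0.38) and -1.15 (SE 0.66).

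By camera with Benjamini-Hochberg adjustment the adjusted p was 0.375 for mesothelial markers, 0.482 for YAP/TAZ targets, 0.474 for SRF targets and for mesenchymal genes, 0.404 for epithelial genes, 0.319 for proliferation and for hypoxia, and 0.805 for p53 targets. With an estimated correlation the adjusted p was 0.922 for p53 targets and 0.918 for the others. Medians and tests differed in sign for proliferation (median -0.05, mean -0.02, test up), epithelial genes (median 0.38, mean 0.13, test down) and SRF targets (median 0.16, mean -0.45, test down). Adjusted over the list alone, 2 SRF targets (Cnn1 and Myl9) and 1 hypoxia gene (Bnip3) passed.

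Other immune, vessel, tissue and stress lists did not pass in the primary comparison, and several of their genes were highest in single tumours. The T cell genes Cd8a, Cd8b1, Cd6 and Lck had log2 fold changes of 2.83 (SE 1.25), 2.49 (SE 1.17), 1.60 (SE 1.05) and 1.77 (SE 1.17), and the last 3 were at 1.305, 0.38 and 0.33 without tumour 14A, with Cd8a from 0.557 CPM in tumour 13 to 52.9 CPM in tumour 14A. The B cell genes Cd79b and Cr2 reached 179 and 60.3 CPM in tumour 14A, and Pax5 and Bank1 were at 1.81 (SE 2.09) and 0.82 (SE 0.95). The complement genes of macrophages C1qa, C1qb and C1qc and the receptor gene Csf1r were at 1.25 (SE 0.64), 1.27 (SE 0.76), 1.301 (SE 0.69) and 0.72 (SE 0.43). The dendritic cell genes Clec9a, Batf3, Ccl17 and Ccl22 were at 1.62 (SE 0.73), 2.60 (SE 1.65), 1.21 (SE 0.80) and 1.81 (SE 1.19).

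Granulocyte genes Ngp, Camp, Hdc and Cxcr2 were at 3.62 (SE 2.12), 3.09 (SE 1.69), -2.21 (SE 1.10) and -1.52 (SE 1.19). The antigen presentation genes Cd74, H2-DMa, H2-Eb1 and Ciita were at 0.32 (SE 0.71), 0.67 (SE 0.55), 0.23 (SE 0.79) and 0.18 (SE 0.65), and the vessel genes Tek, Tie1, Prox1 and Erg at -0.85 (SE 0.32), -0.64 (SE 0.43), -2.12 (SE 1.29) and -0.47 (SE 0.43). The hormone receptor genes Pgr and Esr1 were at -4.44 (SE 1.11) and -1.99 (SE 0.78), and the gonad genes Foxl2 and Inha at 3.91 (SE 1.66) and -1.28 (SE 0.66). Cyp2e1, a liver enzyme gene, ran from 0.124 CPM in tumour 13 to 51.7 CPM in tumour 61, and the gut genes Reg3g, Cdh17 and Lgals4 were at 4.12 (SE 2.04), -0.999 (SE 0.87) and -0.37 (SE 0.42). The stress genes Hspa1b, Hsp90aa1, Hspd1 and Hsph1 were at 1.12 (SE 0.36), 0.68 (SE 0.27), 0.59 (SE 0.28) and -0.96 (SE 0.46).

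The immediate early genes Egr3, Egr2, Atf3 and Zfp36 were at 1.99 (SE 0.49), 1.41 (SE 0.37), 1.87 (SE 1.35) and 0.68 (SE 0.62), and the mitochondrial genes mt-Nd6, mt-Nd5, mt-Nd4 and mt-Nd2 at -0.62 (SE 0.33), -0.67 (SE 0.47), -0.74 (SE 0.53) and -0.82 (SE 0.59). By camera with Benjamini-Hochberg adjustment the adjusted p was 0.482 for T cells, 0.830 for B and plasma cells, 0.248 for macrophages, 0.371 for dendritic cells, 0.440 for neutrophils and for the pancreas, 0.0731 for endothelial cells, and 0.920 for MHC class II and gut epithelium. It was 0.233 for the female reproductive tract and gonad, 0.0673 for heat shock, 0.375 for immediate early genes and 0.319 for mitochondrial mRNA. With an estimated correlation the adjusted p of these 13 lists ran from 0.637 (heat shock) to 0.969 (MHC class II). The endothelial list passed on ranks (adjusted p = 0.0224 by camera with Benjamini-Hochberg adjustment) and without tumour 20 (0.0109) or 59 (6.42e-04), lower, and its adjusted p ran from 6.42e-04 to 0.903 over 22 alternatives. Heat shock passed, higher, without tumour 127 (0.0309) or 59 (0.0335), with 3 groups (0.0498) and without 14A and 127 (0.0360), by camera with Benjamini-Hochberg adjustment (from 0.0200 to 0.637 over 22 alternatives).

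Signs differed for B and plasma cells (median 1.03, mean 1.12, test down), neutrophils (median 0.20, mean 0.25, test down) and gut epithelium (median -0.37, mean 0.92, test down). Adjusted over the list alone, Pgr passed (lower), as did Egr2 and Egr3 (higher). Over all 34 lists 12 passed camera, 10 lower and 2 higher, and 0 passed with an estimated correlation, 11 on ranks, 1 with fry (smooth muscle) and 6 with fry for a change in either direction (smooth muscle, Wnt antagonists, beta-catenin targets, SRF targets, heat shock and the female reproductive tract and gonad).

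Tumour 14B, the secondary tumour, held pancreas and blood transcripts at levels above those of all 4 primary tumours that share its label. Ctrb1, a chymotrypsin precursor gene of the exocrine pancreas, stood at 70311 CPM in tumour 14B, 10360.4 CPM in tumour 14A and at most 21.3 CPM in tumours 13, 59 and 61. Cel and Pnliprp1, lipase genes of pancreatic juice, stood at 19956 and 12613 CPM in tumour 14B and 2183 and 1408 CPM in tumour 14A. The pancreatic enzyme genes Cela1, Ctrl, Rnase1 and Klk1 stood at 22381, 6417, 9526 and 1617 CPM. The haemoglobin genes Hba-a1 and Hbb-bs stood at 316 and 379 CPM, against at most 45.9 and 50.7 CPM, and Rap1gap, which encodes a brake on the GTPase Rap1, at 155 against at most 20.5 CPM.

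Lower in tumour 14B than in all 4 were the genes Btbd11, Mboat1, Tenm3, an adhesion protein gene, Mef2c, a transcription factor gene of muscle and lymphocytes, and Pde4d, which encodes an enzyme that breaks down cyclic AMP. Their log2 differences from the mean of the 4 were -2.68, -1.70, -2.17, -1.43 and -2.04. Kbtbd11, Pgap1, Slc4a8, the granzyme gene Gzmc and the interleukin 18 receptor gene Il18rap were at -1.60, -1.52, -1.44, -2.26 and -1.73. Pancreas genes held 19.0% of counts in tumour 14B and 3.49% in tumour 14A, and 3 pancreas genes had a median log2 difference of 12.39 from the mean of the 4. Epithelial genes, mesothelial markers, neutrophils and B and plasma cells had medians of 2.66, 2.35, 2.21 and 1.98, each above all 10000 random lists. The epithelial and mesothelial lists share the keratin genes Krt8, Krt18 and Krt19, so they are not separate results. Which tissue of the sample their transcripts came from was not tested. Hedgehog genes, the matrix and skeletal muscle had -1.15, -1.13 and -2.77, each below all random lists. Random lists were drawn gene by gene, so a list whose genes move together can lie beyond all of them in a single tumour. By list score, epithelial genes in tumour 14B (3.97) were above all 4 primary tumours (at most 3.64, in tumour 61). The mesothelial, neutrophil, B and plasma cell, Hedgehog, matrix and skeletal muscle scores of tumour 14B lay within the range of the 4. Against tumour 14A alone the medians were 3.16 for pancreas genes, 1.60 for epithelial genes, 1.44 for mesothelial markers and -0.38 for skeletal muscle. The sign turned for the matrix (1.12, above all random lists), Hedgehog genes (0.13), neutrophils (-0.86) and B and plasma cells (-2.36, below all random lists), among others. Of 9937 genes 28 lay above and 9 below all 4 primary tumours by more than 1 log2, and with 1 secondary tumour no test was made.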

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

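The tests of shared reads, of the Hedgehog list and of tumour 14A were chosen only after the result was seen, while the splits of the tumours and the test of a mapping difference were written before the values they measure were seen.

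Rps3a1 was lower and its copies Rps3a2 and Rps3a3 higher in the tumours labelled Pak2-null. If reads were shared out differently among near-identical copies, the summed family should move by under 50% of the log2 fold change of Rps3a1, by more than 2 SE. Its log2 fold change was -0.55 (SE 0.28) against -2.17 for Rps3a1 and 4.84 and 6.45 for the copies, under that bound by less than 2 SE, so shared reads stay open. A mapping difference between the libraries of the 2 groups should put the groups apart in over 50% of copy and parent pairs, with under 25% arguing against it, and they were apart in 41 of 288 (14.2%), close to the 14.0% of all tested genes. A sequence difference between mouse strains was not tested, since reads were not analysed here, and the 5 copies among the 11 genes may not stand for changes in transcription of those loci.

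The Hedgehog list was lower in the tumours labelled Pak2-null, with a median log2 fold change of -0.61 and a mean of -1.28. Without tumour 14A the median was -0.30 (49.7% of it kept) and the mean kept 84.7%, without tumour 19 the median was -0.50 (81.4% kept) and the mean kept 52.2%, and without both, the lowest and the highest tumour, 40.5% and 35.3% were kept. The rule first used the median alone, by which 14A would account for the difference (under 50% kept) and 19 would not; the mean was added after these values were seen, and by median and mean neither tumour alone is decided on. The Pak2 genotype cannot be told from other differences between the groups, since sex patterns run along with the labels in part. Tumours 19 and 20 had the female pattern and the tumours labelled Pak2-null the male one. Wild-type tumour 127 had both Xist (26.6 CPM) and Ddx3y (116 CPM). The exact permutation p of the list scores (0.0571) is the smallest possible and decides nothing. The tissue of tumour 14A, the pathway activity of tumour 19 and the genotype thus all remain possible causes. So do chance (see the splits below), sex and the share of skeletal muscle transcripts, which also separates the groups.

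Tumour 14A was low in matrix transcripts, with a list score of 5.91 against 8.64 to 8.87 in tumours 13, 59 and 61. Transcripts of the pancreas list, at 3.49% of counts, account for 1.79% of this log2 difference of -2.87, which argues against dilution by them. Pancreas transcripts outside the list, such as Cela1 (3127 CPM in tumour 14A), were not counted. If lymphocyte-rich tissue in that sample alone were the cause, tumour 14B should be near the other 3, and its score differed from their mean by -1.87, between the 2 predictions. Tumour 14B was itself above tumours 13, 59 and 61 in B and plasma cell genes (score 4.20 against -0.61, 2.66 and 1.41). In T cell genes it lay among them (2.41 against -1.11, 3.42 and 1.98). It is therefore a poor reference, and this comparison cannot decide. The cause is left undecided.

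With all 35 splits of the 7 primary tumours into 3 and 4, only 1, the real one, called as many as 11 genes, and no other split called more than 0. That is the most extreme outcome that 35 splits allow, so it speaks against chance as the source of that count, copies included, without excluding it. With the copies that passed summed into their parents, the real split also called 0 genes. The other splits were not repeated that way, so nothing is concluded for a count without the copies. The count was also unstable, at 0 without tumour 20, 13, 59 or 61. The copies, sex and the share of skeletal muscle transcripts, which separates the groups as well, are not excluded either. For the lists other splits did as well: counting the real one, 14 of 35 gave the Hedgehog list a camera p as small (lowest 3.25e-06 in another split), 10 the Wnt ligands and receptors (lowest 1.47e-07), 9 the Wnt antagonists (lowest 1.67e-05) and 12 the beta-catenin targets (lowest 0.135), by exact enumeration. In 30 of 35, the real one included, at least 9 other lists passed, with up to 21 in another split. Chance therefore cannot be excluded for these 4 lists or for the number of other lists, and splits of each other list were not counted.

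In 9 of 209 values (175 genes and 34 list scores) 1 of the 4 primary tumours labelled Pak2-null lay far from the other 3, where about 1 in 20 is expected by chance. In log2 CPM, tumour 14A was low in Gli3 (2.10; others 4.90 to 5.28), Myc (5.43; others 6.53 to 6.71) and the p53 target Zmat3 (4.46; others 6.08 to 6.32). It was high in Pcna (7.52; others 5.96 to 6.15), and in the granule gene Ngp (5.51; others -2.03 to -0.85), and low in the matrix score (5.91; others 8.64 to 8.87). Tumour 59 was high in the vessel gene Erg (4.65; others 3.30 to 3.35), tumour 61 in Lep (1.25; others -2.45 to -2.16), and tumour 13 was low in Hsph1 (6.05; others 6.60 to 6.68). Tumour 14A held 6 of the 9. Pgr and Wif1, with at most 3 counts in all 4 tumours, were left out of these values after they were seen.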

How the results depend on the processing

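Other choices were tried for the counts of genes, the lists, the sample structure, the secondary tumour and the genes named with the comparisons. They were not tried for the genes chosen after their values were seen, Rps3a1 and Tpm3 or the tally of copy and parent pairs. Of these choices, leaving out tumours 14A and 127 together, taking out genes of other tissues and both sums of near-identical copies were chosen only after the result was seen. For results that answer a comparison, 116 values stayed the same, 37 were weaker, 11 stronger, 1 moved and 0 changed sign. Some of these results are counts of genes or lists, which cannot change sign, and fry in either direction gives no direction. The 0 says nothing about those. Values counted as the same could still move. The adjusted p of Pak2 went from 0.267 to 0.652 without tumour 127, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was counted as the same, as was a count of 8 genes without tumour 14A against 11. For other gene and list values, 4230 stayed the same, 130 were weaker, 188 stronger, 16 moved and 114 were counted as a change of sign. For list medians of tumour 14B, a change of sign was counted only beyond the spread of the primary tumours labelled Pak2-null. Most of those that turned against tumour 14A alone, given below, are therefore among the values that moved or stayed the same. Of 3961 values of named genes, 59 changed sign, none of them of a gene that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. For the genes that passed, groups that do not overlap all but fixed this in advance. No paired analysis was possible because no label pairs a wild-type tumour with a tumour labelled Pak2-null. A sex covariate was not used, since every tumour labelled Pak2-null had the male pattern and tumour 127 had transcripts of both kinds.

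Adcy2, Limch1 and the other 9 genes that passed kept their direction in every alternative that tested them. That was 23 alternatives for 6 genes and 21 or 22 for the 5 copies, which were not tested where summed. Since the groups did not overlap in these genes, their direction was all but fixed in advance. The number of genes that passed depended on the tool and on single tumours. It was 11 in the primary comparison, 11 with median-of-ratios or upper-quartile normalisation, 12 with library size only, 13 without a filter, 20 with a stricter filter, 25 with limma-voom, 950 with limma-voom and quality weights, 1196 with DESeq2 and 4 with robust dispersion. At unadjusted p under 0.05 there were 1995 in the primary comparison and from 1384 to 3850 in the alternatives. Leaving out a tumour gave 59 (19), 0 (20), 1 (127), 0 (13), 8 (14A), 0 (59) and 0 (61), with 2396, 1486, 1384, 1794, 2543, 1548 and 1869 at unadjusted p under 0.05. Treating all tumours as 3 groups gave 4, the secondary tumour added to the 4 labelled Pak2-null 191, which counts 14A and 14B as separate although the labels do not say whether they share an animal, and 14A and 14B summed 11. Leaving out 14A and 127 together gave 5, and taking out genes of other tissues 22. An adjusted p under 0.1 gave 78, and an absolute log2 fold change of at least 1 gave 11, all by edgeR unless named. The share of lower genes was 72.7% in the primary comparison, 93.2% without 19, 88.0% with the secondary tumour added, 84.6% at 0.1, 62.5% without 14A, 50% with robust dispersion or 3 groups, and 20.0% without 14A and 127.

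Summing copies was first done for the families of Rps3a1, Tpm3, Amd1 with Amd2 and Rpl11 with Gm10036, which gave 1 gene. After that count was seen, the families were replaced by those of every copy that passed (Rps3a1, Tpm3, Cyb5r4 and Lamtor3), which gave 0. Both had 1988 genes at unadjusted p under 0.05. Highest adjusted p values of the 11 genes over the alternatives ran from 0.146 (Rps3a2) to 0.228 (Tpm3-rs7) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

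Pak2 had a log2 fold change of 0.81 with quality weights, where it passed limma-voom with Benjamini-Hochberg adjustment (adjusted p = 0.0480), still higher in the tumours labelled Pak2-null. With 1 tumour left out it ran from 0.66 (without 14A) to 0.98 (without 19) and did not pass, and over 23 alternatives its adjusted p ran from 0.0480 to 0.652 (without 127).

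The Hedgehog list lost its call in 6 of 22 alternatives, with the same direction in the 5 that give one. By camera with Benjamini-Hochberg adjustment its adjusted p was 0.218 with quality weights, 0.169 without 14A and 127, and 2.55e-04 (without 13) to 0.227 (without 14A) with 1 tumour left out. It was 0.637 with an estimated correlation, 0.424 with fry and 0.104 with fry in either direction.

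By camera with Benjamini-Hochberg adjustment, or fry where named, Wnt ligands and receptors had adjusted p values of 0.0793 with quality weights, 0.0656 without 14A and 127, 0.637 with an estimated correlation, 0.424 with fry, 0.419 with fry in either direction, and 1.08e-04 (without 61) to 0.0592 (without 14A) with 1 tumour left out. Wnt antagonists had 0.441 with quality weights, 0.0978 without 14A and 127, 0.637 with an estimated correlation, 0.407 with fry, 0.00401 with fry in either direction, 0.0804 on ranks, 0.0617 with upper-quartile normalisation, 0.0668 with library size only, 0.0832 with 14A and 14B summed, and 0.00897 (without 127) to 0.437 (without 14A) with 1 tumour left out. Beta-catenin targets had 0.0104 with fry in either direction and did not pass otherwise. In either direction fry also passed smooth muscle (0.00888), the female reproductive tract and gonad (0.0104), SRF targets (0.0124) and heat shock (0.0200). Of the other lists 9 passed in the primary comparison, 0 with an estimated correlation, 1 with fry, 4 with fry in either direction, 14 without 14A and 127, 5 without genes of other tissues, and from 8 to 11 with 1 tumour left out.

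Named genes that changed sign did so at small or variable differences. With limma-voom the log2 fold changes were -0.28 for Gli3, -0.58 for Lef1, -0.31 for Ctgf, -0.46 for Msln, -0.0436 for Cd74, -0.12 for H2-Eb1 and -0.21 for Ciita. With quality weights they were -0.49 for Lef1, -0.36 for Ctgf, 0.25 for Wt1, -0.0519 for Ciita, -1.302 for Cd79b, -0.36 for Pax5, -0.56 for Bank1, -1.19 for Ngp, 0.92 for Cxcr2, -0.59 for Batf3, -2.22 for Ctrb1, -0.85 for Atf3 and -3.48e-04 for Zfp36. With the secondary tumour added they were -0.0718 for Gli3 and 0.70 for Muc1.

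Without tumours 14A and 127 the log2 fold changes that changed sign were -3.23 for Lef1, 0.28 for Pak3, -0.0342 for Pcna, -0.0901 for Tk1, -0.23 for Ciita, -2.16 for Cd79b, -2.39 for Pax5 and -0.86 for Bank1. They were -0.0285 for C1qb, -0.13 for Camp, -1.92 for Ngp, -0.89 for Batf3, -0.66 for Atf3 and -0.36 for Zfp36.

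With 1 tumour left out, log2 fold changes of pathway and epithelial genes crossed 0: Gli3 -0.13 (without 59) to 0.48 (without 14A), Lef1 -2.81 (without 14A) to 2.89 (without 19), Ctgf -0.88 (without 13) to 0.96 (without 14A), Msln -0.00751 (without 61) to 1.49 (without 13), Wt1 -1.12 (without 127) to 1.03 (without 19), Krt19 -3.13 (without 127) to 0.42 (without 19), Krt7 -2.50 (without 20) to 0.0460 (without 19) and Cldn3 -4.04 (without 14A) to 0.74 (without 19). So did those of immune and stress genes: Cd74 -0.34 (without 59) to 0.66 (without 13), H2-Eb1 -0.53 (without 59) to 0.72 (without 20), Ciita -0.18 (without 14A) to 0.52 (without 13), Cd79b -1.74 (without 14A) to 3.22 (without 20), Bank1 -0.59 (without 14A) to 1.52 (without 20), Camp -0.17 (without 14A) to 3.50 (without 13), Ngp -1.70 (without 14A) to 4.03 (without 13), Cxcr2 -2.07 (without 127) to 1.53 (without 19), Batf3 -0.95 (without 14A) to 3.00005 (without 13), Atf3 -0.71 (without 14A) to 2.26 (without 13) and Zfp36 -0.21 (without 14A) to 0.92 (without 13).

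Other log2 fold changes of genes named with the comparisons moved by more than 1 without changing sign, and not all of them are given here. Without tumour 19 they were -2.39 for Gli1, -1.20 for Gli2, -0.35 for Ptch1, -1.92 for Scube3, -2.50 for Sfrp5, -0.00 for Cldn7, 4.43 for Twist2, -0.10 for Adm, -0.40 for Hdc and 5.14 for Reg3g. Without 14A they were -3.47 for Muc1, 1.305 for Cd8b1, 0.38 for Cd6, 0.33 for Lck, 0.24 for C1qb, 0.70 for Ccl22 and -7.19 for Pgr. Without 20 they were -1.39 for Actg2, 3.87 for Pax5, -4.18 for Tnni2 and -2.94 for Hspb6, without 127 -0.98 for Eda2r, -0.69 for Prox1 and 5.42 for Foxl2, without 13 3.85 for Dkk2, and without 61 -6.75 for Tnni2 and -7.39 for Mylpf.

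Lists that changed direction under another choice are given with their adjusted p by camera with Benjamini-Hochberg adjustment unless fry is named. Only the matrix list among them had passed before. With quality weights these were the endothelial list (0.903, up), the matrix (0.983, up), p53 targets (0.903, down) and YAP/TAZ targets (0.903, up). Gut epithelium pointed up with 3 groups (0.723), with the secondary tumour added (0.771) and without a filter (0.510). MHC class II pointed down with the secondary tumour added (0.864), with fry (0.976), with 14A and 14B summed (0.929) and on ranks (0.890). B and plasma cells pointed up with the secondary tumour added (0.905).

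Without tumours 14A and 127, lists that turned down were dendritic cells (0.544), immediate early genes (0.971), macrophages (0.211), MHC class II (0.8004), proliferation (0.368) and T cells (0.163). Lists that turned up were the matrix (0.146), the female reproductive tract and gonad (0.971), mitochondrial mRNA (0.905), SRF targets (0.905) and YAP/TAZ targets (0.511). The numbers in brackets are adjusted p values by camera with Benjamini-Hochberg adjustment.

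With 1 tumour left out, the adjusted p by camera with Benjamini-Hochberg adjustment ran as follows for immune lists that changed direction or call: B and plasma cells 0.0125 (without 14A) to 0.844 (without 59), dendritic cells 0.0162 (without 13) to 0.996 (without 14A), macrophages 0.0241 (without 19) to 0.846 (without 127), MHC class II 0.0509 (without 13) to 0.975 (without 127), neutrophils 0.0248 (without 14A) to 0.894 (without 13) and T cells 1.18e-04 (without 13) to 0.844 (without 59). For tumour programmes it ran: epithelial genes 0.0618 (without 61) to 0.819 (without 59), the matrix 9.62e-04 (without 13) to 0.240 (without 14A), hypoxia 0.0320 (without 14A) to 0.981 (without 19), mesenchymal genes 5.88e-04 (without 14A) to 0.823 (without 13), mesothelial markers 0.0296 (without 127) to 0.899 (without 13), p53 targets 0.407 (without 127) to 0.848 (without 61), proliferation 2.79e-10 (without 19) to 0.694 (without 127), SRF targets 0.135 (without 13) to 0.893 (without 19) and YAP/TAZ targets 0.130 (without 13) to 0.903 (without 19). Endothelial cells ran 6.42e-04 (without 59) to 0.615 (without 19), heat shock 0.0309 (without 127) to 0.217 (without 19), gut epithelium 0.604 (without 20) to 0.911 (without 61) and mitochondrial mRNA 8.30e-07 (without 19) to 0.975 (without 127). Leaving out 14A turned the direction of the matrix, dendritic, T cell, MHC class II, SRF and YAP/TAZ lists, and leaving out 19 that of epithelial, gut, hypoxia, mesothelial, MHC class II, neutrophil and p53 lists. Leaving out 13 turned B cell, epithelial, gut, mesenchymal, mesothelial and neutrophil lists, 20 B cell, gut, mitochondrial and proliferation lists, 59 gut and MHC class II, 61 B cell and p53 lists, and 127 macrophage, mitochondrial and proliferation lists.

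Lists that passed only under another choice, by camera with Benjamini-Hochberg adjustment, were endothelial cells on ranks (0.0224, down), heat shock with 3 groups (0.0498, up), and the pancreas without a filter (1.16e-04, up) and with 3 groups (0.0147, up). With quality weights they were mitochondrial mRNA (0.00112, down) and proliferation (4.88e-04, up). Without tumours 14A and 127 they were B and plasma cells (0.00121, down), epithelial genes (0.0254, down), heat shock (0.0360, up), hypoxia (0.0254, down), mesenchymal genes (2.30e-04, up), mesothelial markers (0.0360, down) and neutrophils (0.0118, down).

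Against tumour 14A alone, rather than the mean of 4, pancreas genes in tumour 14B had a median log2 difference of 3.16 instead of 12.39. Medians that turned from below to above 0 were those of mesenchymal genes (1.40), the matrix (1.12), MAPK outputs (0.78), Wnt antagonists (0.76), Wnt ligands and receptors (0.51), YAP/TAZ targets (0.47), fibroblasts and pericytes (0.44), SRF targets (0.40) and Hedgehog genes (0.13). Those that turned from above to below 0 were T cells (-2.63), B and plasma cells (-2.36), neutrophils (-0.86), immediate early genes (-0.22), the interferon response (-0.15), gut epithelium (-0.06) and p53 targets (-0.01).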

Other observations

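Myod1 and Myog, transcription factor genes that commit cells to muscle, stood at 9.09, 102 and 338 CPM and 17.6, 267 and 856 CPM in tumours 19, 20 and 127. In the primary tumours labelled Pak2-null they reached at most 2.77 and 5.60 CPM, in tumour 61. The muscle stem cell gene Pax7 stood at 0.788, 27.5 and 67.4 CPM in the wild-type tumours. Myh3 and Myh8, the embryonic and perinatal myosin genes, stood at 2491 and 2037 CPM in tumour 127, and Myh4, an adult fast myosin gene, at 3829.5 CPM in tumour 20. Together Myh3 and Myh8 made up 45.1% of the 5 myosin genes' CPM in tumour 127, 7.44% in tumour 20 and 10.5% in tumour 19. These genes, and all in this part, were chosen after their values were seen.

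H19, the noncoding neighbour of Igf2, stood at 6153, 3485 and 4496 CPM in tumours 19, 20 and 127 and at most 61.8 CPM in the primary tumours labelled Pak2-null, and the cell cycle inhibitor gene Cdkn1c at 60.8, 68.2 and 124 CPM and at most 11.1 CPM. Their log2 fold changes were -7.02 (SE 1.03) and -3.73 (SE 0.50), with adjusted p values of 0.0809 and 0.0590 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Itgam, an integrin gene of myeloid cells, stood at 1026 and 1205 CPM in tumours 14A and 14B and at most 152 CPM elsewhere, and Spi1, the transcription factor gene of that lineage, at 612 and 545 CPM and at most 126 CPM. The collagen gene Col1a1 stood at 425 and 926 CPM in these 2 tumours and from 5549.8 to 10386 CPM in the other 6.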
